A study of Gallus gallus with 8 samples.

How the data were processed

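Small RNA was sequenced from the ectoderm of the chick frontonasal ectodermal zone, a signalling region of the embryonic face that later expresses Sonic hedgehog (SHH). Per the labels, untreated embryos were taken at Hamburger-Hamilton stage 18 (HH18, 48 h of incubation) and stage 22 (HH22, 72 h), with 4 samples per stage and 2 chicks pooled in each sample. Total RNA was isolated with a miRNeasy kit and libraries were made with an Illumina TruSeq small RNA kit, per the labels' protocols. The submitters' processing notes name bcl2fastq, cutadapt 1.8.1 and kallisto 0.44.0. Their order, the reference sequences and the genome build are not given in the sources used here, so no genomic coordinates are printed.

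The deposited table holds 1 value per miRNA and library for 994 features, on a log2-like scale. The labels do not state how these log2 values were made, and the following was worked out from the deposited values themselves. Every library has the same lowest value, 8.52, which is the value of 0 reads under the closed-form variance-stabilizing transformation of counts. Inverting that transformation gave, in each library, values that were whole multiples of 1 step within a tolerance of 0.001, for 100% of the values above 0. The inverse of the step equalled the median-of-ratios size factor computed over the 200 features with reads in all 8 libraries. The inverted values are called normalized counts below, and the whole multiples are called reads. Because kallisto estimates counts, a read here is an estimated count that the authors' processing had rounded. Similar miRNAs can share such estimates: let-7a-5p and let-7j-5p had identical reads in every library, as did miR-204 and miR-211, so members of these pairs cannot be told apart. All 8 columns were matched to a sample by name. Of the 994 features, 942 had a name found among the miRNA genes of the RefSeq annotation of the GRCg7b assembly, which was used only for names and for which genes neighbour each other.

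The libraries held 6276121 to 88471588 reads, and 1 read was worth between 0.3355 and 4.1814 normalized counts. A floor of 3 reads therefore stood at 1.01 to 12.54 normalized counts, depending on the library. Intervals and floors cover counting error only, since PCR copies were not removed by molecular identifiers as far as the labels say. Replicates of a stage differed by far more than sampling noise (chi-square per degree of freedom of 283 or more in every pair), so each library was counted once. The p-values therefore describe pools of 2 chicks, not single embryos. The sample numbers 1 to 8 are all different, so no samples were paired.

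The test fixed before the data were examined was a count model, with limma-trend on log2(value + 1) named for the case of normalized values. Because the deposited values are log2 values and not counts, the second was used. Features with a normalized count of at least 1 in at least 4 libraries were tested on log2(normalized count + 1), HH22 against HH18, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale and, most of all for scarce miRNAs, can lie above or below the ratio of the means. Versions were R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A fold against a stage with 0 reads is a lower bound against a floor of 3 reads over the 4 libraries of the stage. With 1 to 3 reads the ratio is given with an exact 95% binomial interval.

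miRNAs were named by a rule fixed before the data were examined. It took the tested members of the miR-199 and miR-214 list; the 10 largest rises and 10 largest falls past the threshold with a mean normalized count of at least 10 and no overlap between stages; the 5 most abundant miRNAs of each stage; and the 2 most abundant tested members of each fixed list. Another 27 miRNAs are named in the text that were chosen after their values were seen, and this is said where they appear. The 14 lists were miR-199 and miR-214, epithelial, neural, mesenchyme and smooth muscle, striated muscle, blood and endothelium, Hox cluster, placode and eye, let-7 and lin-4, miR-302 and miR-367 (with miR-1811), miR-17/92 and paralogs, miR-130 and miR-301, liver and gut, and the Z-linked sex-biased miR-2954. Lists with at least 3 tested members (12 lists) were tested with camera at a preset correlation of 0.01, which compares a list with all other tested features, again with Benjamini-Hochberg adjustment.

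The procedure was tested on simulated counts for the comparison of HH22 with HH18, drawn for 651 features from the observed means, spread and size factors, with 200 features changed per run over 10 runs. On average 450.1 simulated features were tested. It recovered 24.6% of 2-fold and 41.3% of 4-fold changes among all tested features, and 97.3% and 100% among features with a mean of at least 1000. Of the calls, 1.32% were false, and 0 calls were made when nothing was changed. The planted list change was found in 10 of 10 runs. The simulated features were drawn independently of each other, whereas members of real lists vary together (estimated correlation 0.71 for blood and endothelium, 0.13 for miR-302 and miR-367). More simulated features were tested than the 356 of the data. The false rate and the list recovery therefore do not carry over to the list tests or to scarce miRNAs.

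Alternatives fixed beforehand were scaling by library size, scaling by library size without the 5 most abundant features, no filter, a minimum CPM of 10, a minimum normalized count of 10, pseudocounts of 0.1 and 10, robust variance shrinkage, voom with sample quality weights, reads summed by family and arm, an estimated correlation between list members, the fry rotation test, and each library left out in turn. Added after the data were seen were TMM scaling (30% of the fold changes and 5% of the abundances trimmed), the deposited values as they stand, a moderated quasi-Poisson test of the recovered reads, every library thinned to the depth of the shallowest, a limma test against a fold of 1.5, and leaving out HH18 replicates 5 and 6 together. Of the alternatives planned beforehand, those that fit a negative binomial model were not run. The recovered reads were tested with voom and the quasi-Poisson test, and the size factors planned for 1 of those not run are already in the deposited values.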

Results

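Small RNA from the ectoderm of the chick frontonasal ectodermal zone was compared between HH18, before SHH is expressed there, and HH22, after its onset. Each stage had 4 samples, and each sample pooled 2 chicks. The HH18 libraries held 12740243, 6276121, 31318393 and 26034882 reads (replicates 5 to 8) and the HH22 libraries 88471588, 46912793, 48716487 and 50083999 reads (replicates 1 to 4). The mean depth was 19.1 ± 11.6 M (mega) reads (SD, n = 4) at HH18 and 58.5 ± 19.99 M reads (SD, n = 4) at HH22, with no overlap between the stages (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). Depth and stage were thus confounded, and no depth range held libraries of both stages. Of 994 miRNA features, 651 had reads in at least 1 library and 356 were tested.

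The ectoderm was dominated by a small number of miRNAs at both stages. miR-100-5p, a partner of let-7 in its genomic clusters, made up 64.5% ± 2.6 of the reads at HH18 and 70.3% ± 1.7 at HH22 (SD, n = 4). miR-99a-5p followed with 11.1% ± 0.78 and 10.4% ± 0.42 (SD, n = 4). miR-183, which is abundant in sensory placodes and hair cells, took 10.4% ± 2.1 of the reads at HH18 and 5.36% ± 0.93 at HH22 (SD, n = 4). The 5 most abundant miRNAs together held 93.4% ± 1.1 and 91.3% ± 0.99 of the reads (SD, n = 4). On normalized counts, miR-183 fell from 2982470 to 1610600 (log2 fold change -0.88, SE 0.21, limma adjusted p = 0.0188). That call was lost without HH18 replicate 8 or HH22 replicates 2 or 3 (limma adjusted p = 0.0539, 0.0636 and 0.0619). The other miRNAs among the 5 most abundant of a stage, apart from miR-148a-3p, did not pass the threshold: miR-100-5p had a log2 fold change of 0.20 (SE 0.16), miR-99a-5p of -0.02 (SE 0.13), miR-92-3p of -0.45 (SE 0.15) and miR-125b-5p of -0.17 (SE 0.16). The sign for miR-100-5p turned to -0.26 when libraries were scaled without the 5 most abundant features, and that for miR-99a-5p to 0.055 under TMM scaling. Scaled without the 5 most abundant features, miR-99a-5p (log2 fold change -0.49, limma adjusted p = 0.0294), miR-125b-5p (-0.63, adjusted p = 0.0156) and miR-92-3p (-0.92, adjusted p = 0.00511) passed as lower. miR-92-3p also passed as lower with library size scaling, with a minimum CPM of 10 and without HH18 replicate 7 (adjusted p = 0.0234, 0.0287 and 0.0316).

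Between the stages, 52 of 356 tested miRNAs passed the threshold, 35 of them higher and 17 lower at HH22 (limma-trend, Benjamini-Hochberg adjusted p under 0.05). Counted once where features have the same reads in every library, the 52 were 51. Of the higher miRNAs 26 rose at least 2-fold, and 12 of the lower fell at least 2-fold. In 50 of the 52 the 4 HH22 values did not overlap the 4 HH18 values. Among all tested miRNAs 20.2% showed no overlap, against 2.86% by chance. Of 79 tested miRNAs with a mean of at least 1000 normalized counts, 22 were higher and 8 lower. Of 101 with a mean of 100 to 1000, 1 was higher and 8 were lower. Of 136 with a mean of 10 to 100, 6 were higher and 1 lower, and of 40 with a mean under 10, 6 were higher and 0 lower. Scaling the libraries without the 5 most abundant features lowered the median log2 fold change of the tested miRNAs by 0.43 (a median difference of -0.43), and 71 miRNAs then passed, 24 higher and 47 lower. The number past the threshold was 27, 29, 29 and 27 without HH22 replicates 1, 2, 3 and 4, and 53 without HH18 replicates 5 and 6, which stood apart on the first 2 principal components (32.6% and 24.98% of the variance). They were also the shallowest libraries. Among HH18 libraries the first component fell as depth rose (33.0, 24.9, 5.03 and -10.4 for replicates 6, 5, 8 and 7). HH18 replicate 7, the deepest of them, lay within the HH22 range (-15.9 to -9.11). Depth was therefore not separated from what set replicates 5 and 6 apart.

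**Figure D1:**
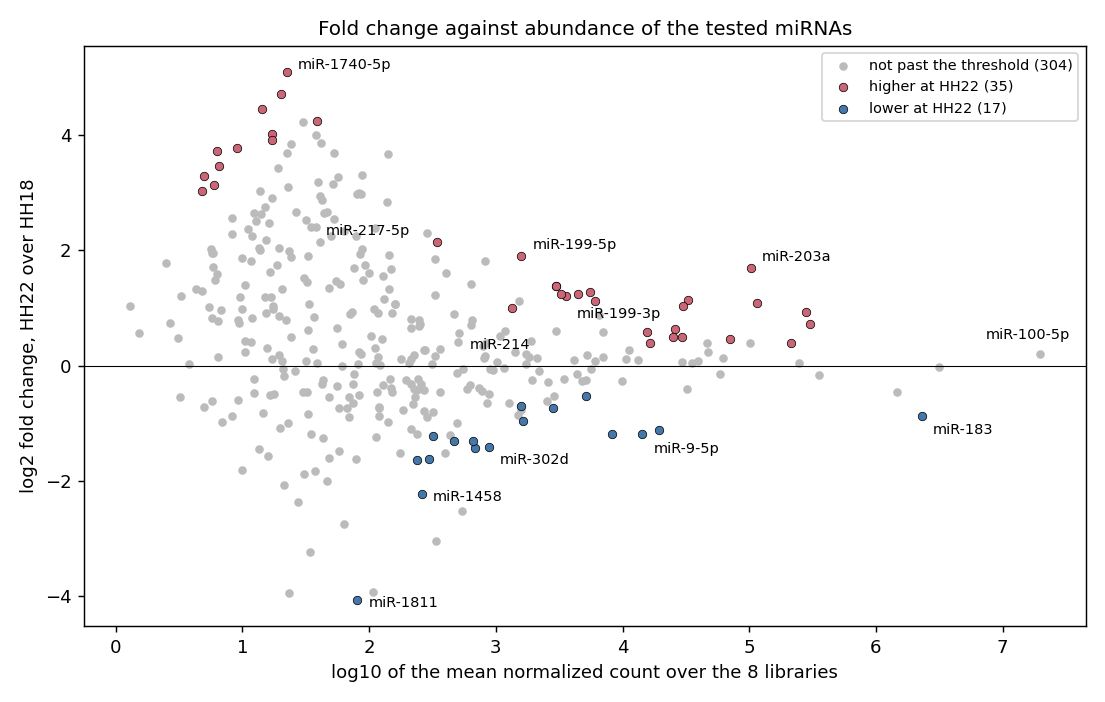
Each point is 1 of the 356 tested miRNAs, with the log10 of its mean normalized count over the 8 libraries on the x axis and its log2 fold change, HH22 over HH18, on the y axis. Red points (35) were higher and blue points (17) lower at HH22 past the threshold, and the largest positive fold changes belong to miRNAs with a mean under 100.

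The comparison was made to find miRNAs that change around the onset of SHH expression, and the title of the series names the miR-199 family. Both arms of miR-199, a miRNA known from mesenchyme, were higher at HH22. miR-199-5p rose 3.74-fold, from 672 ± 97 to 2510 ± 336 normalized counts (SD, n = 4), with no overlap between stages (log2 fold change 1.90, SE 0.19, limma adjusted p = 0.000183). miR-199-3p rose 2.30-fold, from 2302 ± 1379 to 4834 ± 1010 (SD, n = 4; log2 fold change 1.20, SE 0.32, limma adjusted p = 0.0304). miR-214, whose gene neighbours the miR-199 gene MIR199A2 with 0 genes between them in the GRCg7b annotation, measured 441 ± 278 at HH18 and 587 ± 112 at HH22 (SD, n = 4) and did not pass (log2 fold change 0.57, SE 0.38, limma adjusted p = 0.385). Thus 2 of the 3 tested members rose, and 2 when adjusted over the list alone. miR-199b had 0 to 5 reads per library and was not tested. As a list, the members had a camera adjusted p of 0.0544, and an adjusted p = 0.28 with an estimated correlation. The list passed as higher in some alternatives, among them voom (camera adjusted p = 0.0068), thinning to equal depth (0.049) and without HH18 replicate 6 (0.011). It did not pass in others, among them library size scaling (0.0767), scaling without the 5 most abundant features (0.194) and without HH18 replicate 7 (0.178).

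Single HH18 libraries set the spread of miR-199-3p and miR-214. HH18 replicate 5 held 4363 normalized counts of miR-199-3p against 1451 to 1710 in the other HH18 libraries, and the same library had the highest sum of blood and endothelial miRNAs of the 8. Without it the log2 fold change was 1.56 (limma adjusted p = 0.000876), whereas the call was lost without any of HH18 replicates 6, 7 and 8 (adjusted p = 0.0738, 0.0682 and 0.0796) or HH22 replicates 2, 3 and 4 (adjusted p = 0.0864, 0.0865 and 0.0561). HH18 replicate 6 held 857 normalized counts of miR-214 against 284 to 322 in the other HH18 libraries. Without it miR-214 passed, with a log2 fold change of 0.94 (limma adjusted p = 0.043). The call for miR-199-3p was also lost when libraries were scaled without the 5 most abundant features (log2 fold change 0.74, limma adjusted p = 0.207).

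**Figure D2:**
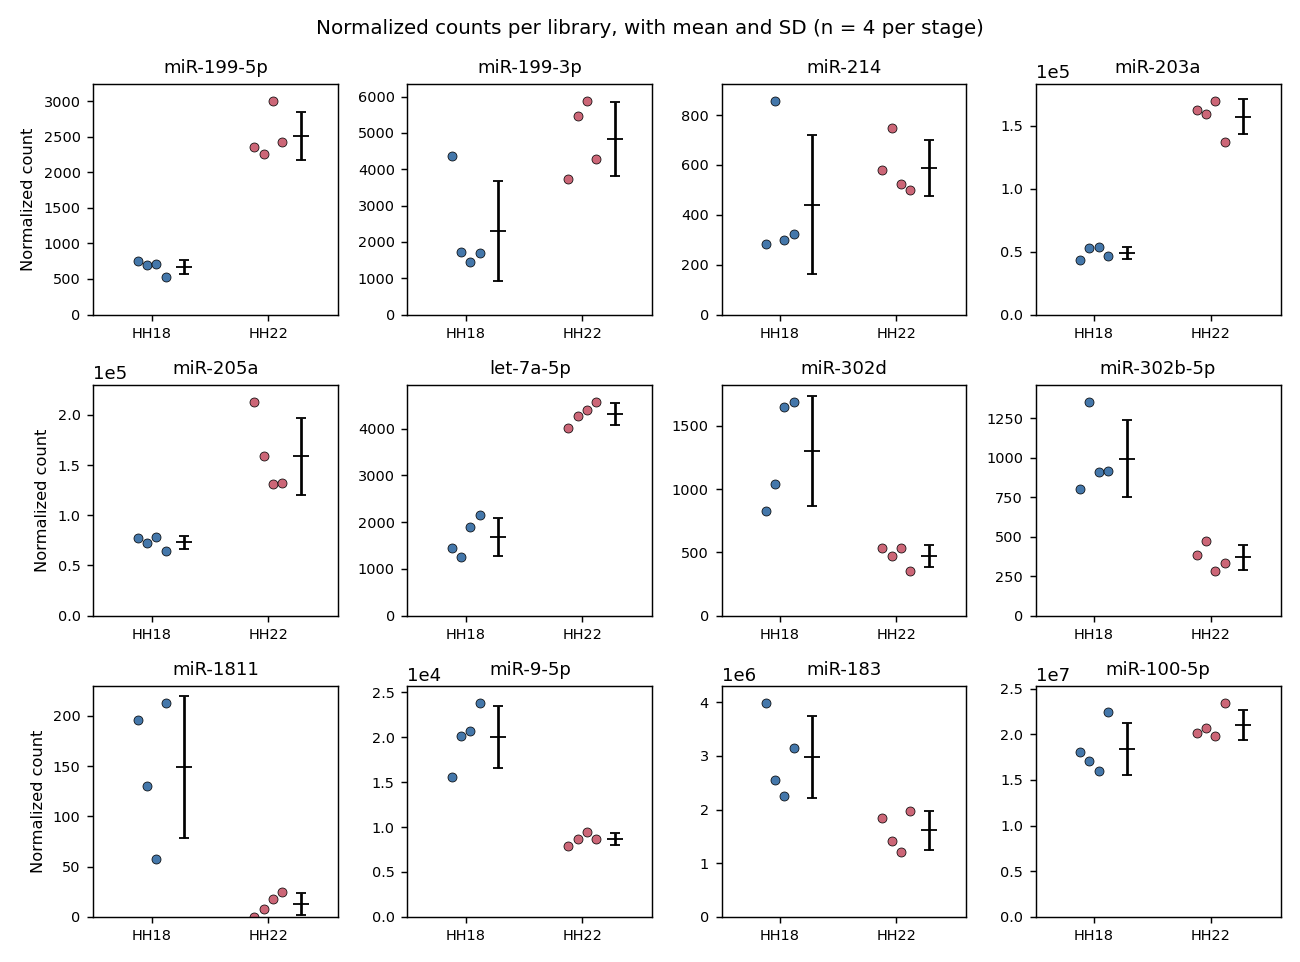
Normalized counts of 12 miRNAs in each HH18 (blue) and HH22 (red) library, on linear axes from 0, with horizontal marks for the mean and bars for the SD (n = 4 per stage). The 4 HH22 values of miR-199-5p lie above all HH18 values, while 1 HH18 library reaches the HH22 range for miR-199-3p (4363) and for miR-214 (857).

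Among epithelial miRNAs, miR-203a and miR-205a rose, while the miR-200 family did not rise past the threshold. miR-203a, which promotes keratinocyte differentiation, rose 3.22-fold, from 48955 ± 4819 to 157387 ± 14125 normalized counts (SD, n = 4; log2 fold change 1.69, SE 0.11, limma adjusted p = 4.82e-06). miR-205a rose 2.13-fold, from 73107 ± 6504 to 158680 ± 38303 (SD, n = 4; SE of the log2 fold change 0.16, limma adjusted p = 0.000911). Of 9 tested members 2 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone, the added one being miR-205b (log2 fold change 0.90, SE 0.29). It passed over all tested features without HH18 replicate 8 (limma adjusted p = 0.0367), under TMM scaling and with a minimum CPM of 10. The sum of its reads with those of miR-205a also passed, but that sum is nearly all miR-205a (mean normalized count 115893 against 468). The member that fell was miR-200b-5p, the less abundant arm of its precursor, from 11428 ± 2207 to 5051 ± 1008 (SD, n = 4). The abundant arms miR-200b-3p and miR-200a-3p had log2 fold changes of 0.13 (SE 0.21) and 0.40 (SE 0.18), and both turned negative (-0.34 and -0.0697) when libraries were scaled without the 5 most abundant features. These members other than miR-203a and miR-205a were chosen after their values were seen. The list as a whole had a camera adjusted p of 0.229, and an adjusted p = 0.687 with an estimated correlation.

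Members of the let-7 family, whose levels rise with developmental time in many animals, were more abundant at HH22. let-7a-5p rose 2.61-fold, from 1687 ± 409.5 to 4313 ± 229 normalized counts (SD, n = 4; log2 fold change 1.38, SE 0.19, limma adjusted p = 0.000911). let-7j-5p has the same reads and is not a separate measurement. let-7f-5p rose 2.43-fold and let-7c-5p 2.18-fold, both chosen after their values were seen. Of 15 tested members of the let-7 and lin-4 list, 4 rose (let-7j-5p among them, so 3 distinct measurements) and 0 fell, over all tested features and when adjusted over the list alone. The abundant cluster partners miR-100-5p, miR-99a-5p and miR-125b-5p were not among them. Scaled without the 5 most abundant features, 4 rose and 3 fell, miR-99a-5p and miR-125b-5p among the latter. The list had a camera adjusted p of 0.125, and an adjusted p = 0.464 with an estimated correlation.

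Tested miRNAs of the miR-302 and miR-367 cluster, which is active in early embryonic and pluripotent cells, were lower at HH22. All were miR-302 features or miR-1811, and no miR-367 feature was tested. Of 7 tested members 5 fell and 0 rose, and 6 fell when adjusted over the list alone. The number that fell depended on single libraries: it was 4, 5, 4 and 2 without HH18 replicates 5, 6, 7 and 8, and 2, 3, 3 and 2 without HH22 replicates 1, 2, 3 and 4. It was 2 with no filter, 0 against a fold of 1.5, 6 by voom and 7 by the quasi-Poisson test. Without HH18 replicate 8 or HH22 replicates 1 or 4, miR-302d and miR-302b-5p passed and miR-302a did not (limma adjusted p = 0.0518, 0.0647 and 0.0561). miR-302d fell from 1299 ± 435 to 471 ± 86 normalized counts (SD, n = 4; log2 fold change -1.42, SE 0.29, limma adjusted p = 0.00956). miR-302b-5p fell from 995 ± 245 to 369 ± 81 (SD, n = 4; log2 fold change -1.43), and miR-302a from 945 ± 280 to 374 ± 93 (SD, n = 4; log2 fold change -1.31). miR-1811, whose gene lies between MIR302A and MIR302C in the GRCg7b annotation, had the largest fall of any miRNA past the threshold, from 149 ± 71 to 12.5 ± 10.9 (SD, n = 4; log2 fold change -4.07, SE 1.20, limma adjusted p = 0.0473), and passed in 12 of 23 alternatives. miR-302c-5p was just past the threshold (log2 fold change -1.62, SE 0.49, limma adjusted p = 0.0499) and passed in 9 of 24 alternatives. The other members, miR-302c-3p (log2 fold change -1.003, SE 0.34) and miR-302b-3p (-0.32, SE 1.28), both chosen after their values were seen, did not pass over all tested features. HH18 replicate 6 held 4.18 normalized counts of miR-302b-3p (1 read) against 290.9 to 509.1 in the other HH18 libraries, and without it miR-302b-3p passed, with a log2 fold change of -1.90 (limma adjusted p = 0.0206), as did miR-302c-3p (-1.21, adjusted p = 0.0376), which passed in 6 of 24 alternatives. miR-302b-3p also passed in the quasi-Poisson test (adjusted p = 0.0102). The list had a camera adjusted p of 2.22e-05, and an adjusted p = 0.11 with an estimated correlation. It was the 1 list of 12 past the threshold with the preset correlation, and 0 lists passed with an estimated one.

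The neural list moved in both directions in single members. miR-9-5p, abundant in neural progenitors, fell from 20034 ± 3403 to 8660 ± 626 normalized counts (SD, n = 4; log2 fold change -1.20, SE 0.14, limma adjusted p = 0.000489). miR-219a, known from oligodendrocytes and chosen after its values were seen, rose from 2777 ± 1348 to 6092 ± 900 (SD, n = 4; log2 fold change 1.25, SE 0.29, limma adjusted p = 0.0188). The call of miR-219a was lost without HH22 replicate 1 (limma adjusted p = 0.0595), with no filter (adjusted p = 0.0533) and against a fold of 1.5. Thus 1 of 19 members rose and 1 fell, also when adjusted over the list alone. miR-128-3p had a log2 fold change of 0.05 (SE 0.14), which was -0.03 with library size scaling and -0.42 without the 5 most abundant features, where it passed as lower (limma adjusted p = 0.0255) and 1 member rose and 3 fell in all. The list had a camera adjusted p of 0.568, and an adjusted p = 0.687 with an estimated correlation.

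Lists for other tissues showed few calls. In the mesenchyme and smooth muscle list 1 of 8 members rose (2 without HH18 replicates 5 or 7), miR-140-3p, known from cartilage, from 24276 ± 1422 to 34206 ± 1694 (SD, n = 4; log2 fold change 0.50, SE 0.10, limma adjusted p = 0.00797). Scaled without the 5 most abundant features, miR-140-3p had a log2 fold change of 0.0286 and did not pass, and miR-21-5p went from 0.23 (SE 0.16) to -0.24. With library size scaling or against a fold of 1.5, miR-140-3p did not pass either. In the Hox cluster list 1 of 4 rose, miR-10b-5p, from 1949 ± 1026 to 4580 ± 2019 (SD, n = 4; log2 fold change 1.25, SE 0.37, limma adjusted p = 0.0487, past the threshold in 8 of 24 alternatives, and with 1 library left out only without HH18 replicate 6 or HH22 replicate 3). miR-10a-5p had a log2 fold change of 0.10 (SE 0.15), which was -0.36 when scaled without the 5 most abundant features. With reads summed by family and arm, the sum that holds it together with miR-10b-5p had 0.56 (limma adjusted p = 0.0484). Adjusted over the list alone, miR-196-5p, chosen after its values were seen, also passed, with 202 ± 255 normalized counts at HH18 and 13.3 ± 17.2 at HH22 (SD, n = 4; log2 fold change -3.92). HH18 replicate 6 held 581 of these against 44.6 to 124.7 in the other HH18 libraries, and without it the log2 fold change was -3.16 (limma adjusted p = 0.151 over all tested features). Over all tested features miR-196-5p passed in 1 of 23 alternatives, when scaled without the 5 most abundant features (adjusted p = 0.0449). In the placode and eye list 1 of 5 fell, miR-183, with 2 falling when scaled without the 5 most abundant features, while miR-375 had a log2 fold change of 0.08 (SE 0.19), which was -0.38 when scaled without the 5 most abundant features. In the miR-17/92 list 1 of 17 fell (2 without HH18 replicate 7, with miR-92-3p), miR-92-5p, from 2152 ± 444 to 1097 ± 132 (SD, n = 4; log2 fold change -0.96, SE 0.20, limma adjusted p = 0.00959). The counts of these 4 lists were the same when adjusted over the list alone, apart from miR-196-5p, and their camera adjusted p were 0.673, 0.673, 0.257 and 0.673.

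In the remaining lists, with 1 exception, no member rose or fell past the threshold. The exception was the striated muscle list, in which 1 of 3 rose. It was miR-133a-3p, chosen after its values were seen, with 0 reads in the 4 HH18 libraries and 9.92 ± 5.35 normalized counts at HH22 (SD, n = 4), at least 8.496-fold higher. miR-1a-3p and miR-499-5p stood at 9.37 ± 6.32 and 8.34 ± 5.96 at HH22 (SD, n = 4) and 2.00 ± 4.00 and 3.40 ± 6.79 at HH18 (SD, n = 4). Of 10 members of the miR-130 and miR-301 list 0 passed by limma, also when adjusted over the list alone, and 3 had an unadjusted p under 0.05. These were miR-130b-5p (log2 fold change -0.53, SE 0.21), miR-301a-3p (1.81, SE 0.60, limma adjusted p = 0.0779) and miR-130a-3p (1.13, SE 0.49), the latter pair chosen after their values were seen. By voom 0 passed, with 3 at an unadjusted p under 0.05, and by the quasi-Poisson test 1 passed, miR-301a-3p. Without HH18 replicate 5 miR-301a-3p (limma adjusted p = 0.0262) and miR-130b-5p (adjusted p = 0.0375) passed, and without HH18 replicate 7 miR-301a-3p did (adjusted p = 0.0423). The most abundant member, miR-130b-3p, had a log2 fold change of -0.27 (SE 0.15). Scaled without the 5 most abundant features, 3 members passed by limma as lower: miR-130b-3p (log2 fold change -0.74, adjusted p = 0.0043), miR-130b-5p (-1.001, adjusted p = 0.0044) and miR-130a-5p (-0.92, adjusted p = 0.0456), chosen after its values were seen. With a minimum CPM of 10, miR-301a-3p passed (adjusted p = 0.0415). The 8 blood and endothelium members gave 0 calls by limma, also when adjusted over the list alone, 0 by voom or the quasi-Poisson test, and 0 at an unadjusted p under 0.05 in any of these. In that list miR-451 and miR-142-5p varied between libraries of a stage, at 978 ± 1810.9 and 1000.3 ± 1342 at HH18 and 203.4 ± 230 and 85.9 ± 162 at HH22 (SD, n = 4). The liver and gut members miR-215-5p (32.8 ± 59.7 at HH18 and 70.9 ± 25.2 at HH22, SD, n = 4) and miR-194 (27.9 ± 26.1 and 20.2 ± 8.0, SD, n = 4) did not pass, and 0 of these 2 had an unadjusted p under 0.05 by limma. Without HH18 replicate 5, which held 122.4 normalized counts of miR-215-5p against 0 to 4.79 in the other HH18 libraries, miR-215-5p passed as higher (log2 fold change 4.47, limma adjusted p = 0.0246). The Z-linked miR-2954, which is higher in male birds, measured 37090 ± 8548 at HH18 and 27779 ± 4164 at HH22 (SD, n = 4; limma adjusted p = 0.181) and passed as lower when adjusted over its list of 1, and over all tested features when scaled without the 5 most abundant features (log2 fold change -0.87, adjusted p = 0.00975) and without HH18 replicate 7 (adjusted p = 0.0434). The camera adjusted p of the striated muscle, blood and endothelium, and miR-130 and miR-301 lists were 0.246, 0.245 and 0.703. Camera compares the test statistics of a list, not its fold changes, with those of the other tested features, so that rises with a large SE count little. It pointed down for the neural, placode and eye, miR-17/92, and miR-130 and miR-301 lists, although their mean and median log2 fold changes were above 0. For the miR-130 and miR-301 list the median (0.77) was also above that of all tested miRNAs (0.38). The direction thus does not mean that its fold changes were lower.

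**Figure D3:**
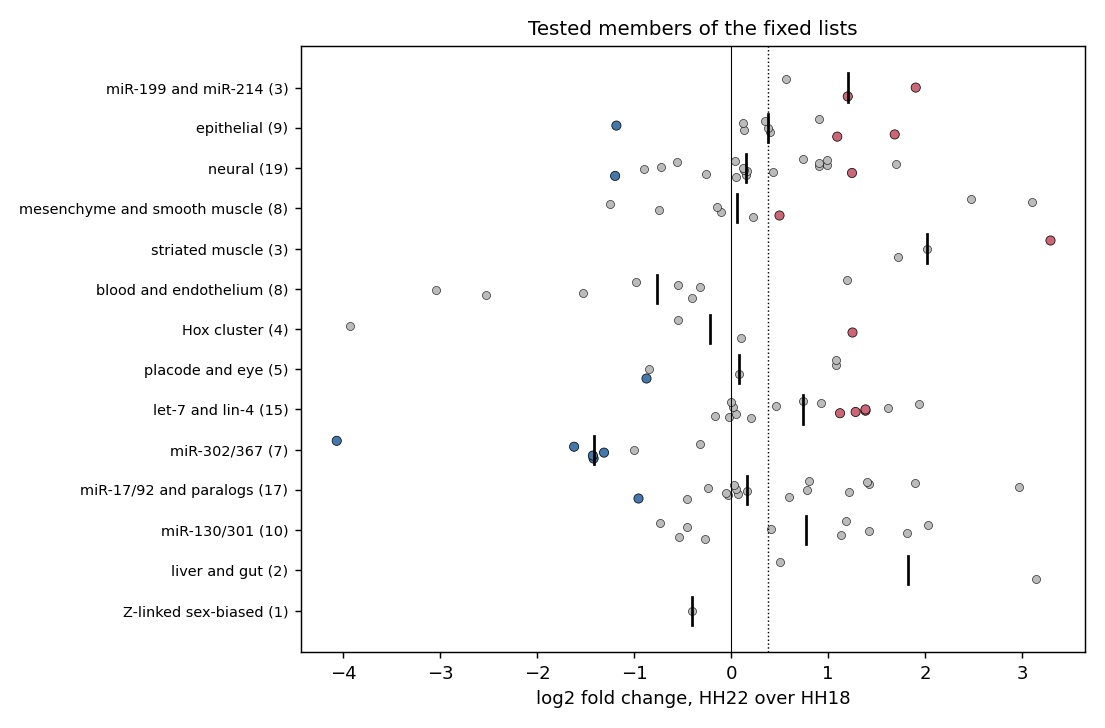
Each point is a tested member of a fixed list, with its log2 fold change, HH22 over HH18, on the x axis and the lists with their number of tested members on the y axis; red and blue points passed the threshold as higher and lower, black bars are list medians and the dotted line is the median of the 356 tested miRNAs (0.38). The miR-302 and miR-367 list members lie to the left, with a median of -1.42.

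Outside the lists, several abundant miRNAs rose. miR-148a-3p rose 1.66-fold, from 225385 ± 19282 to 372584 ± 19404 normalized counts (SD, n = 4; limma adjusted p = 0.000911), and did not pass when scaled without the 5 most abundant features (log2 fold change 0.26). miR-181a-5p (1.91-fold), miR-30a-5p (2.05-fold) and miR-101-3p (2.19-fold), chosen after their values were seen, had limma adjusted p of 0.00151, 0.000911 and 0.000911. miR-217-5p rose from 115 ± 35 to 574 ± 335 (SD, n = 4; log2 fold change 2.14, SE 0.51, limma adjusted p = 0.0188). miR-217-5p passed in 18 of 23 alternatives, and not without HH22 replicates 3 or 4 (limma adjusted p = 0.0802 and 0.069), by voom (adjusted p = 0.158), by the quasi-Poisson test (adjusted p = 0.0979) or against a fold of 1.5. Among falls outside the lists, miR-1458 went from 418 ± 156 to 105.6 ± 72 (SD, n = 4), miR-1648-5p from 355 ± 56 to 121.7 ± 55 (SD, n = 4), miR-1306-5p from 663 ± 62 to 275 ± 74 (SD, n = 4) and miR-1674 from 448 ± 51 to 191.7 ± 6.6 (SD, n = 4). Their log2 fold changes were -2.23, -1.63, -1.31 and -1.21, and they passed in 15, 17, 23 and 19 of 24 alternatives. Leaving out 1 library ended the call of miR-1458 for HH18 replicates 5, 6 and 8 and HH22 replicates 1, 2 and 4 (limma adjusted p up to 0.101). It ended that of miR-1648-5p for HH18 replicates 7 and 8 and HH22 replicates 1, 2 and 3 (adjusted p up to 0.0865), and that of miR-1674 for each HH22 replicate (adjusted p up to 0.079).

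The largest positive fold changes belonged to scarce miRNAs that were nearly absent at HH18. miR-1740-5p had 0 reads in the 4 HH18 libraries and 348 reads at HH22 (44.9 ± 32.4 normalized counts, SD, n = 4), at least 39.95-fold higher. miR-1765 had 1 read at HH18 and 273 at HH22, a ratio of 94.0 (exact 95% interval 16.7 to 3727). miR-107-5p had 1 and 222 reads (ratio 76.5, interval 13.6 to 3034), and miR-101-2-5p 2 and 236 reads (ratio 40.6, interval 11.1 to 338). HH22 replicate 2 had 3 of the reads of miR-101-2-5p, which passed in 5 of 22 alternatives. miR-33-5p, encoded within a gene of sterol regulation, went from 5.01 ± 6.88 to 72.9 ± 26.9 normalized counts (SD, n = 4), and miR-34c-3p from 3.00 ± 5.99 to 31.1 ± 9.3 (SD, n = 4); they passed in 13 and 6 of 23 alternatives. With 1 library left out, miR-33-5p passed without HH18 replicates 5 or 7, miR-34c-3p without HH18 replicate 7, and miR-101-2-5p without HH18 replicate 7 or HH22 replicate 2. In all, 12 miRNAs with a mean under 100 were called higher. Of these 0 were called without the filter or by the quasi-Poisson test of reads, and 8 after every library was thinned to the depth of the shallowest. Without HH18 replicates 5, 6, 7 and 8 in turn 8, 5, 12 and 5 were called. Without an HH22 library 7 of the 12 could not be tested, since fewer than 4 libraries then reached the filter, and 2 or 3 of the other 5 were called.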

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

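The tests of depth, loss, mesenchyme, scaling and blood in this part were chosen after the results they bear on were seen. The splits of the libraries were chosen before their results were seen, except that those of the miR-302 and miR-367 list were added after the list itself and the splits of the list count had been seen. Among the groups of 4 libraries checked, Dixon's test (95% level) picked out 20 values far from the other 3 of their stage. Chance would give about 1 in 20 groups, or 7.5 here, if the values were normally distributed. That rate does not hold for linear counts of scarce miRNAs. Wherever the other 3 libraries had no reads, any read at all was picked out. This was so at HH18 for miR-1765, miR-107-5p, miR-34c-3p, miR-101-2-5p, miR-499-5p and miR-1a-3p. The 20 values therefore cannot be read as an excess over chance.

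Among abundant miRNAs, HH18 replicate 5 was high for miR-199-3p (4363 normalized counts against 1451 to 1710), HH18 replicate 6 for miR-214 (857 against 284 to 322) and miR-196-5p (581 against 44.6 to 124.7), HH18 replicate 8 for miR-302c-5p (761 against 300.1 to 366.8), HH22 replicate 3 for miR-148a-3p (401523 against 360034 to 364763), and HH22 replicate 1 for miR-103-3p (20375 against 17903 to 18302). Among scarce miRNAs, HH18 replicate 7 was high for miR-33-5p (15.2 against 0 to 2.55), and alone had reads among the HH18 libraries for miR-34c-3p (11.99), miR-101-2-5p (1.598), miR-499-5p (13.6) and miR-1a-3p (7.99). It was the deepest HH18 library (31.32 M reads), with reads of 382 features against 273 to 336 in the other HH18 libraries. Whether its depth accounts for these values was not tested. HH18 replicate 5 alone had reads of miR-1765 (2.31) and HH18 replicate 8 alone of miR-107-5p (1.27). HH22 replicate 2 had 0 of miR-1a-3p against 11.4 to 13.7. The depth of HH22 replicate 1 was 88.47 M (mega) reads against 46.91 to 50.08 M reads. HH18 replicate 5 was also high for miR-215-5p (122.4 against 0 to 4.79).

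Blood and endothelial miRNAs set HH18 replicate 5 apart. Their summed normalized count was 14371 there against 233 to 2041 in the other HH18 libraries, and 2084 in HH22 replicate 4 against 306 to 343 in the other HH22 libraries; miR-451 reached 3694 in HH18 replicate 5 (25.5 to 113 in the others), and miR-142-5p 329 in HH22 replicate 4 (0.568 to 11.7). Since the sum picked the library, each member was set against the HH18 library picked by the sum of the members at the other loci (4 loci in all): 8 of 8 members were highest in it, and it was HH18 replicate 5 each time, for erythroid (miR-451, miR-144), leukocyte (miR-142, miR-223) and endothelial (miR-126) members alike, so blood or vessel tissue in the dissected ectoderm may be the source. No explanation beyond this was tested. A raised sum occurred at both stages, but that of HH22 replicate 4 was far below that of HH18 replicate 5 and close to that of HH18 replicate 6 (2041). Without HH18 replicate 5, 55 miRNAs passed the threshold, 42 of them among the 52.

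The rise of miR-199-5p was weighed against more mesenchyme in the HH22 samples: more of an otherwise constant mesenchyme would raise miR-214 and both arms of miR-199 alike. The log2 of miR-199-5p over miR-214 was 0.77 ± 0.76 at HH18 and 2.10 ± 0.40 at HH22 (SD, n = 4), a difference of 1.336 (exact permutation p = 0.0286, adjusted p = 0.0457 over 8 ratios), and over miR-140-3p and miR-21-5p it was higher by 1.41 and 1.67 (p = 0.0286 and adjusted p = 0.0457 each), which goes against it. These values leave it open, since miR-140-3p and miR-21-5p stood at 24276 and 43647 normalized counts at HH18, where a small share of mesenchyme would not show, since miR-199-3p over miR-214 differed by 0.64 (exact permutation p = 0.371) and miR-199-5p over miR-199-3p by 0.70 (p = 0.0571), and since without HH18 replicate 6, the library high for miR-214, the differences over miR-214 were 0.98 (p = 0.0571, as without HH22 replicates 1, 3 or 4) and 0.17 (p = 0.743), so more mesenchyme cannot be told apart from a change with stage. The scaling that lowers HH22 values most, without the 5 most abundant features, left a log2 fold change of 1.44 (limma adjusted p = 0.00173; 8.17e-05 to 0.00286 over the 24 alternatives) and thinning to equal depth left 1.90, which argues against scaling and depth as the whole cause. For the 2 family members past the threshold, 1 of 35 splits of the libraries, the real one, gave as many, and the highest other gave 0. That is the smallest share that 35 splits can give, so chance is made less likely but is not excluded.

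The 12 scarce rises coincide with libraries 3.07 times deeper at HH22. By a cutoff set after the rises were seen, at most 6 staying called in libraries thinned to one depth was to count for depth. In fact 8 stayed called, miR-33-5p and miR-1641 close to the threshold (limma adjusted p = 0.0468 and 0.0411). Within limits, this argues against depth as the whole cause for those 8. Thinning was a single random draw. Thinned reads were scaled up to about the worth of a read in the shallowest library with the pseudocount kept at 1, which stretches contrasts with 0. The number called also depends on that scale: unthinned, with a pseudocount of 10, 6 of the 12 were called. Of the other 4, 2 were too scarce to be tested after thinning. Of the 2 still tested, 1 dropped by more than its SE (miR-34c-3p, log2 fold change from 4.03, SE 1.17, to 2.48). The other dropped by less (miR-101-2-5p, from 3.92, SE 1.18, to 3.02), so for these 4 depth cannot be told apart from stage. Scarce miRNAs were also shifted up as a class. The median log2 fold change was 1.11 at a mean under 10 and 1.05 at 10 to 100, against -0.06 at 100 to 1000 and 0.13 at 1000 or more. The 12 rises were not shown to be particular changes within that shift. Loss of scarce miRNAs from the HH18 libraries was the other candidate. Of 23 miRNAs with 10 to 100 normalized counts at HH18 and read in all 4 HH18 libraries, 0 were nearly absent (at most 1 read) from each HH22 library. Of 98 with 10 to 100 at HH22 and read in all 4 HH22 libraries, 7 were nearly absent from each HH18 library. These 7 were 116.1 times the number expected if the HH18 libraries lost scarce miRNAs independently (0.0603). Libraries did not lose them independently, however, since pairs of HH18 libraries both lacked a scarce miRNA 1.55 times as often as independence gives, and pairs of HH22 libraries 2.66 times, so loss cannot be told apart from a change with stage.

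For the number of miRNAs past the threshold, the real split gave 52 and the highest of the other 34 splits 1, so 1 of 35 splits gave as many. That is the smallest share that 35 splits can give. The other 34 mix libraries of both stages, so a difference between stages lowers their counts. Chance is thus made less likely but is not excluded. The number of lists does not stand out from chance: 29 of 35 splits gave at least 1 list with the preset correlation, and the highest other gave 5. For the miR-302 and miR-367 list itself 1 of 35 splits, the real one, gave so small a camera p (1.85e-06, or 5.73 as -log10 p), though the highest other reached 5.38 as -log10 p, close to it.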

How the results depend on the processing

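Of the 26 alternatives, TMM scaling, the deposited values, the quasi-Poisson test, thinning, the test against a fold of 1.5 and leaving out HH18 replicates 5 and 6 together were chosen after the data were seen. Across the alternatives that gave a value, the 72 named miRNAs kept direction and side of the threshold in 1371 of 1689 instances, while 240 lost the call, 37 gained one and 41 changed sign. With reads summed by family and arm, a miRNA was given the value of the sum that holds it. These counts, and the numbers of alternatives passed, include such values. Of the 45 named miRNAs past the threshold, 6 stayed past it in each alternative that tested them. miR-199-5p, miR-203a, let-7a-5p (with let-7j-5p), let-7f-5p and miR-9-5p passed in each of their 24 alternatives, with log2 fold changes of 1.44 to 2.03, 1.22 to 1.76, 0.92 to 1.51, 0.82 to 1.40 and -1.66 to -1.11 (deposited values aside). miR-199-3p passed in 15 of 24, miR-183 in 19 and miR-34c-3p in 6 of 23. With every library thinned to the depth of the shallowest, 332 features were tested and 48 passed, 47 of them among the 52. The median SE of the log2 fold change was 1.14 at a mean under 10 and 1.47 at 10 to 100, against 0.18 at 1000 or more.

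The number of miRNAs past the threshold was 52, and 24 with no filter (651 features tested) and 10 against a fold of 1.5, where the null is stricter. Leaving out 1 library gave 27 to 66, lowest without HH22 replicates 1 and 4 (27 each) and 2 and 3 (29 each), where the filter left 45 of the 52 tested; without HH18 replicates 5, 6, 7 and 8 it was 55, 40, 66 and 35. Of the 52, 27 to 48 were then shared, and the rest of the cause was not tested. Between 38 and 52 passed under other scalings, filters, pseudocounts and tests, apart from the 24 and 10 above and 71 when scaled without the 5 most abundant features; without HH18 replicates 5 and 6 together 53 passed, 36 of them among the 52. Members of the miR-199 and miR-214 list past the threshold numbered 2, and 1 when scaled without the 5 most abundant features, with no filter or against a fold of 1.5, 3 without HH18 replicates 5 and 6, and 1 to 2 with 1 library left out (1 without HH18 replicates 7 or 8 or HH22 replicates 2, 3 or 4). Lists past the threshold numbered 1, and 3 with no filter, with voom, with reads summed by family and arm, and without HH18 replicates 5 and 6; 2 with a pseudocount of 10, with the deposited values and after thinning; 0 with an estimated correlation; 5 with fry, which asks another question; and 1 to 2 with 1 library left out (2 without HH18 replicates 5 or 6 or HH22 replicates 1, 3 or 4). The miR-302 and miR-367 list passed in each camera alternative with the preset correlation. Wherever 2 or 3 lists passed, the miR-199 and miR-214 list was among them. With reads summed by family and arm the epithelial list passed (camera adjusted p = 0.0167), but it was not the same list. Its miR-200 members are listed by letter, which the sums do not carry, so they dropped out. The cause of the other changes in the lists was not tested.

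Among miRNAs past the threshold, miR-181b-5p, miR-26a-5p and miR-103-3p changed sign when scaled without the 5 most abundant features (log2 fold changes -0.0080, -0.0685 and -0.0756). With reads summed by family and arm, the sum that holds miR-30c-1-3p had 0.38. The sum that holds miR-130a-3p, not past the threshold, had -0.094. Both were counted as changes of sign but are values of the sums, not of the single miRNAs. The other changes of sign were in results not past the threshold. When scaled without the 5 most abundant features, which lowers HH22 values as a whole, log2 fold changes were -0.26 for miR-100-5p, -0.42 for miR-128-3p (then past the threshold, limma adjusted p = 0.0255), -0.24 for miR-21-5p, -0.36 for miR-10a-5p, -0.38 for miR-375, -0.0697 for miR-200a-3p and -0.34 for miR-200b-3p, and the camera adjusted p of mesenchyme and smooth muscle was 0.849. Without HH18 replicates 5 and 6 they were -0.089 for miR-128-3p, -0.062 for miR-21-5p, 1.499 for miR-451, 2.22 for miR-142-5p, -0.025 for miR-10a-5p, -0.16 for miR-375, -0.96 for miR-194 and -0.23 for miR-200b-3p, and 0.492 was the adjusted p of blood and endothelium. With voom they were -0.0032 for miR-128-3p, 0.39 for miR-451 and -0.029 for miR-194; with library size, -0.0305 for miR-128-3p; with TMM, 0.055 for miR-99a-5p. miR-194 was -0.046 with a pseudocount of 10, -0.00033 in the deposited values and -0.44 in the quasi-Poisson test. With fry, adjusted p were 0.745 for neural, 0.602 for miR-17/92 and 0.694 for miR-130 and miR-301, which fry sets against 0 and not against other features. With 1 library left out the ranges were -0.082 to 0.034 for miR-99a-5p, -0.083 to 0.11 for miR-128-3p, -1.31 to 1.07 for miR-451, -0.10 to 0.18 for miR-375, -0.77 to 1.23 for miR-194, -0.013 to 0.27 for miR-200b-3p, -1.90 to 0.31 for miR-302b-3p, and an adjusted p of 0.0747 to 0.942 for blood and endothelium. The cause was not tested further. Negative binomial models, planned beforehand, were not run; voom and the quasi-Poisson test used the recovered reads.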

Other observations

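The families and miRNAs of this part were chosen after their values were seen, and the splits for the arms were chosen before their result was seen. Beyond the lists, several families of abundant miRNAs had members that rose at HH22. Of 10 tested miR-30 features 3 rose (miR-30a-5p, miR-30d and miR-30e-3p) and 1 fell (miR-30c-1-3p). miR-30a-5p went from 19909 ± 4019 to 40309 ± 3559 normalized counts and miR-30d from 20467 ± 2774 to 31524 ± 3230 (SD, n = 4), whereas miR-30c-1-3p went from 1941 ± 317 to 1191 ± 152 (SD, n = 4). The summed reads of the miR-30 3p arms, among them the more abundant miR-30e-3p, had a log2 fold change of 0.38. Both miR-181a-5p and miR-181b-5p rose among 4 tested miR-181 features, by 1.91-fold and 1.37-fold. miR-26a-5p (1.32-fold), miR-103-3p (1.31-fold), miR-221-3p (1.505-fold) and miR-15c-5p (2.00-fold) rose as well. Of their 24 alternatives, miR-26a-5p and miR-181b-5p passed in 7, miR-103-3p in 10, miR-15c-5p in 12, miR-30c-1-3p in 15, miR-30e-3p in 18, and miR-30d and miR-221-3p in 21. With 1 library left out, miR-26a-5p stayed past the threshold only without HH18 replicate 7, miR-181b-5p without HH18 replicate 7 or HH22 replicate 3, miR-103-3p without HH18 replicates 5 or 7, and miR-15c-5p without HH18 replicates 5, 7 or 8 (limma adjusted p otherwise up to 0.150, 0.139, 0.1005 and 0.101). miR-30e-3p was lost without HH22 replicates 1 or 4, and miR-30c-1-3p without HH22 replicates 2, 3 or 4. Scaling without the 5 most abundant features lowers log2 fold changes (a median shift of -0.47 over miRNAs with a mean of at least 100), and miR-181b-5p, miR-26a-5p and miR-103-3p then changed sign, to -0.0080, -0.0685 and -0.0756.

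The 2 arms of one precursor did not always change alike. Among 31 precursors with at least 100 normalized counts of each arm, the log2 ratio of the 5p to the 3p arm passed the threshold for 1, miR-1677, where it went from 4.34 at HH18 to 2.99 at HH22 (difference -1.35, SE 0.23, limma adjusted p = 0.0148), and 9 had an unadjusted p under 0.05. For miR-200b the ratio went from -2.37 to -3.68 (difference -1.31, SE 0.34, limma adjusted p = 0.0807), which does not pass. A ratio of arms does not depend on the scaling of the libraries. The hypothesis that arms change unequally with stage may be set against chance: 1 of 35 splits of the libraries, the real one, gave a precursor past the threshold, and the highest other gave 0. That is the smallest share that 35 splits can give, so chance is made less likely but is not excluded. The splits count precursors past the threshold and do not test miR-1677 by itself. Whether processing, arm stability or the assignment of reads to similar sequences differs was not tested.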
